A study of Mus musculus with 16 samples.

How the data were processed

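RNA of cultured FAPs from wild-type and Il4ra knockout mice, given vehicle or recombinant IL-4, was hybridised to 16 Illumina MouseRef-8 v2.0 bead arrays, 4 per group, per the labels. The RNA was purified on RNeasy columns and labelled with Cy3 per the labels. The dose and time of IL-4, the sex of the mice and the chip of each array were not given in the sources used here. Groups were taken from the sample titles. The deposited table holds 1 value per probe and array on a scale read as log2; it was normalized by the authors, since the sorted values of any 2 arrays differ by at most 0.00059, as quantile normalization gives. Software, background correction, detection calls and log base were not given in the sources used here. Log2 was inferred from the deposited values, which run from 7.72 to 14.77, and a variance-stabilizing transform that is close to log2 only at high values cannot be told from it. The normalization gives every array the same distribution, so a change of total RNA per cell would not be seen, and the floor compresses changes of dim genes.

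Genes were named through the platform's probe annotation: 23978 probes had 1 symbol, 0 had several and 1719 had no name here. Of the named probes 23962 matched the RefSeq table of assembly GRCm38 by Entrez number, and 0 symbols changed. No probe was named Il4ra, so the planned check of the knockout by its targeted gene was not made, and Mki67 and Ccnb1, which the fixed rule also named, are not analysed here.

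Everything else was computed from the deposited log2 values with R 4.3.3 and limma 3.58.1, without further normalization or filter. One linear model with a mean per group was fitted to all 16 arrays (12 residual degrees of freedom), with empirical Bayes moderation. The 5 contrasts were IL-4 minus vehicle in wild type, the same in the knockout, the difference of these responses, knockout minus wild type under vehicle, and knockout minus wild type under IL-4. P-values are two-sided and adjusted by Benjamini-Hochberg over the 25697 probes of a contrast, with a threshold of 0.05. The last 3 contrasts share arrays with the first 2, so their results are not independent of them.

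Gene lists, the rule for named genes, the design and most alternatives were fixed before the data were examined. The 20 lists cover IL-4 and STAT6 target genes, IL-4 receptor and signalling components, DNA replication and G1/S, G2/M and mitosis, adipogenesis and lipid storage, extracellular matrix and fibroblast activation, FAP and mesenchymal progenitor identity, inflammatory cytokines and chemokines, interferon-stimulated genes, phagocytosis and lysosomal clearance, secreted factors acting on myogenic cells, cholesterol biosynthesis, the unfolded protein and integrated stress response, immediate early and heat shock genes, ribosomal proteins, and markers of myogenic cells, macrophages and leukocytes, endothelium, pericytes and smooth muscle, and tenocytes and Schwann cells. Of 581 list entries 520 were measured, and the brightest probe stood for a gene. Each list was tested against all other genes with camera (preset correlation 0.01), adjusted over 100 tests of lists and contrasts, and again with an estimated correlation. The named genes were, for the wild-type response, up to 12 with the largest rise and 12 with the largest fall among those past the threshold with 1 symbol and groups that do not overlap, and 8 and 8 for the other contrasts; up to 2 rising and 2 falling members per list; and a fixed set of 13 genes, of which 11 were measured.

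On data simulated for the wild-type response with known changes, the same code recovered 91.9% of probes changed by 0.25, 99.7% of those changed by 0.5 and 100% of those changed by 1 on the log2 scale. It called 45 of 127485 unchanged probes, and 0 probes in a contrast without change. The changed probes were drawn at random from all probes, of which 56.4% lie within 0.15 of the array minimum. The simulation did not compress changes there, so the shares recovered need not hold for real changes or for probes with a larger spread. In the real data Rpl5, for instance, differed by 0.44 between genotypes under vehicle and did not pass (limma adjusted p = 0.123). The number of arrays limits the precision. Alternatives were another quantile normalization, median centring, filters on dim probes, an offset of 50, a trended and robust variance model, array weights, stricter thresholds, only the groups compared, the replicate number as a block, other set tests and each array left out. Figures were drawn with matplotlib 3.10.9.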

Results

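Gene expression was measured in cultured fibro/adipogenic progenitors (FAPs), the mesenchymal progenitor cells of skeletal muscle that can form fibroblasts and adipocytes. The cells came from Balb/cJ mice, either wild type or lacking the interleukin-4 (IL-4) receptor alpha chain (Il4ra knockout), and were given vehicle or recombinant IL-4, a type 2 cytokine that signals through this receptor to STAT6. Each of the 4 groups had 4 arrays, which the series describes as biological replicates. The 16 arrays were Illumina mouse bead arrays with 25697 probes, of which 23978 carried 1 gene symbol. Values lay on a scale read here as log2, with a median of 7.85 on every array. Folds below hold under that reading, and 56.4% of the probes lay within 0.15 of the array minimum, where differences are compressed. No probe was named Il4ra, so the genotype labels were not checked by the targeted gene. The first principal component held 60.3% of the variance and set the 4 wild-type IL-4 arrays, at 18.71 to 20.81, apart from the other 12, which lay between -8.15 and -4.10. The second component, with 12.4%, set the knockout arrays (0.92 to 5.45) apart from the wild-type vehicle arrays (-9.33 to -6.56). On it the wild-type IL-4 arrays lay at -3.77, 0.80, 3.36 and 3.72, partly within the knockout range, so it did not separate the genotypes as such.

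The first comparison asked what IL-4 changes in wild-type FAPs. The largest rise was that of Car4, a carbonic anhydrase, from 7.80 ± 0.02 to 12.13 ± 0.15 (mean ± SD, n = 4 arrays each), a log2 change of 4.33 ± 0.05 (SE) or 20.1-fold. Ccl11, the eosinophil chemoattractant eotaxin, rose 8.46-fold (log2 change 3.08 ± 0.09), and Cish, a feedback inhibitor of cytokine signalling, rose 4.35-fold (2.12 ± 0.03). Il13ra2, the decoy receptor for interleukin-13, rose 3.41-fold (1.77 ± 0.03). Car4 and Il13ra2 lay near the array minimum under vehicle, so their folds depend on that floor. The genes with the largest falls were led by Itga11, a collagen-binding integrin subunit, which fell by 1.74 ± 0.06 on the log2 scale, and Dio3, the deiodinase that inactivates thyroid hormone, which fell by 1.49 ± 0.08. In total 3510 probes passed an adjusted p of 0.05 in limma, 1630 higher and 1880 lower with IL-4, and most changes were small: their median size was 0.24, and 62 rises and 18 falls reached 2-fold. A fold of at least 1.5 was reached by 343 of them.

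Among the 12 largest rises were also Daglb, a diacylglycerol lipase (log2 change 3.27), Aif1l (2.52), Pcolce2, a procollagen processing enhancer (2.47), Edn1, the precursor of endothelin-1 (1.92), Serpina3n (1.91), Mylk, the myosin light chain kinase (1.80), Col6a2, a collagen VI chain (1.70), and Igfbp5, an insulin-like growth factor binding protein (1.70). The falls included Kng1 (-1.46), the scavenger receptor Scara5 (-1.39), Lyz1 (-1.32), the cyclin-dependent kinase inhibitor Cdkn1c (-1.30), Angptl7 (-1.21), the angiotensin receptor Agtr1a (-1.12), Igfbp4 (-1.11), Tmem86a (-1.11), the growth factor Bmp4 (-1.10) and the alcohol dehydrogenase Adh1 (-1.09). Adjusted p-values of these 24 genes in limma ranged from 1.54e-16 for Car4 to 3.97e-07 for Tmem86a. Of the 3 probes each for Itga11 and Kng1, 2 passed in the stated direction, and of the 3 for Lyz1, 1 did. Arg1, a gene induced by IL-4 in macrophages, lay at 7.83 ± 0.02 under vehicle and 7.85 ± 0.02 with IL-4 (n = 4 each; limma adjusted p = 0.718), close to the array minimum. Il6 (log2 change 0.02, adjusted p = 0.76), Fabp4 (-0.04, 0.49), Socs1 (0.06, 0.131), Pdgfra (-0.07, 0.832) and Col1a1 (0.18, 0.428) did not pass either. Socs1 passed without wild-type IL-4 array 5 and with the trended, robust variance model (adjusted p = 0.0343).

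**Figure D1:**
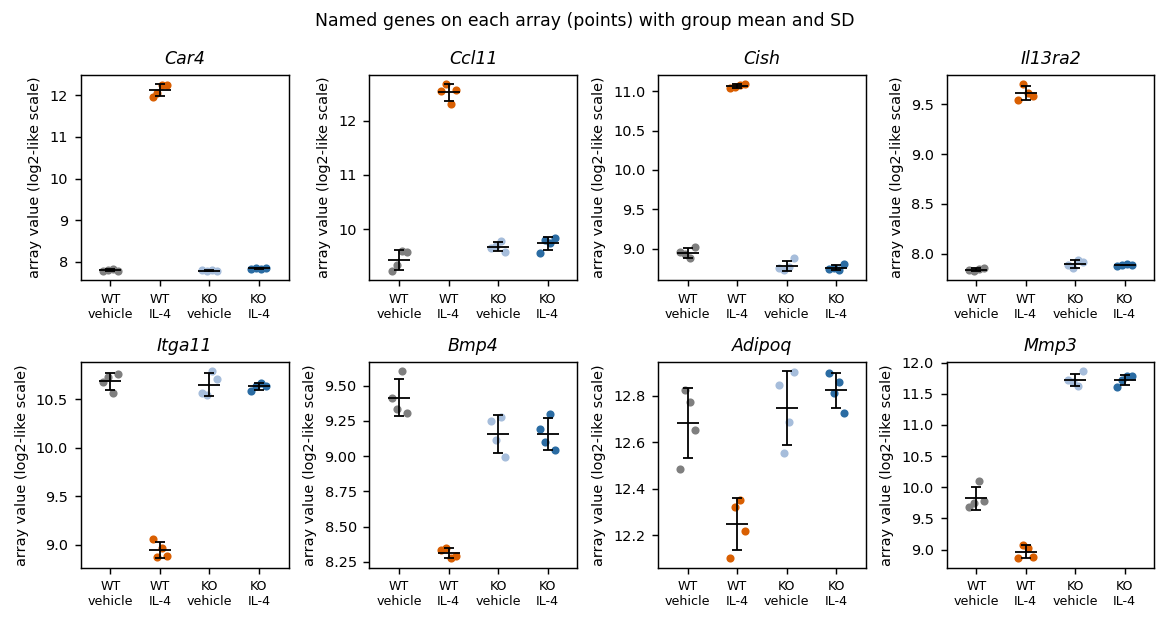
Array values on the log2-like scale (vertical axes, which do not start at 0) of 8 named genes in the 4 groups; points are the 4 arrays of a group, and bars give the mean and SD. With IL-4 the wild-type arrays moved for Car4, Ccl11, Cish, Il13ra2, Itga11, Bmp4 and Adipoq, and Mmp3 fell by 0.86; Mmp3 was at 11.72 in knockout vehicle arrays against 9.82 in wild-type vehicle arrays.

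Cell-cycle genes rose together with IL-4 in wild-type FAPs. Of 43 measured genes of DNA replication and the G1/S transition, 32 rose and 1 fell (35 and 1 adjusted over the list alone), with a median log2 change of 0.33. Mcm5, a subunit of the replicative helicase, rose by 1.07 ± 0.03 (SE), Mcm10 by 0.61 ± 0.03 and Mcm2 by 0.51 ± 0.03. The primase gene Prim1 fell by 0.04 ± 0.01. That call ended without wild-type vehicle arrays 1 or 3 or wild-type IL-4 array 7, with the trended, robust variance model (adjusted p = 0.0516) and with only the groups compared (0.0922). Of 46 genes of G2/M and mitosis, 32 rose and 0 fell (33 and 0 adjusted over the list alone), with a median of 0.22; the centromeric histone Cenpa rose by 1.42 ± 0.05 and the mitotic kinase Plk1 by 0.97 ± 0.04. Both lists passed camera, a test of a list against all other genes, with adjusted p = 8.65e-33 and 1.26e-32. With an estimated correlation the adjusted p-values were 5.48e-06 and 1.23e-06.

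Genes of adipogenesis and lipid storage fell. Of 38 measured, 21 fell and 0 rose (23 and 0 adjusted over the list alone), with a median log2 change of -0.23 (camera adjusted p = 5.56e-11; adjusted p = 0.000264 with an estimated correlation). Pnpla2, the adipose triglyceride lipase, fell by 0.49 ± 0.03 (SE), and the glycerol channel Aqp7 fell by 0.74 ± 0.07. Adipoq, the gene of adiponectin, fell by 0.44 ± 0.08 from 12.68 ± 0.15 (SD, n = 4), and Pparg, the master regulator of adipocyte differentiation, fell by 0.26 ± 0.05 (2 of its 3 probes passed).

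IL-4 and STAT6 target genes fixed beforehand rose as a list, with 10 of 34 higher and 1 lower (12 and 1 adjusted over the list alone). Their mean log2 change was 0.35 and their median 0.02 (camera adjusted p = 1.18e-05; adjusted p = 0.0102 with an estimated correlation), so the change lay in a minority of members, among them Cish, Il13ra2 and Ccl11. The lymphoid transcription factor Irf4 fell by 0.16 ± 0.03 (SE). Genes of the unfolded protein and integrated stress response also rose, 8 of 21 higher and 0 lower (10 and 0 over the list alone; median 0.07; camera adjusted p = 1.83e-06, and adjusted p = 0.0013 with an estimated correlation). Slc7a5, an amino acid transporter, rose by 0.84 ± 0.06 and Pdia4, a disulfide isomerase of the endoplasmic reticulum, by 0.66 ± 0.06. Of 23 secreted factors acting on myogenic cells, 9 fell and 1 rose (10 and 2 over the list alone; median -0.03; camera adjusted p = 0.0113, and adjusted p = 0.029 with an estimated correlation). Bmp4 and the activin antagonist Fst (fell by 0.85 ± 0.08) were lower, and Il15 was higher by 0.42 ± 0.04. Among 21 genes of FAP and mesenchymal progenitor identity, 10 rose and 4 fell (11 and 4 over the list alone; median 0.12; camera adjusted p = 0.0136). That call was lost with an estimated correlation (adjusted p = 0.0892) and in the brighter part of the probes (adjusted p = 0.0559). Vim rose by 0.84 ± 0.08 and Hic1 by 0.43 ± 0.04, while Twist2 fell by 0.36 ± 0.03 and Meox1 by 0.23 ± 0.02.

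Other lists moved in both directions or hardly at all in wild type. Of 39 genes of the extracellular matrix and fibroblast activation, 8 rose and 11 fell (11 and 11 adjusted over the list alone; camera adjusted p = 0.957). Col6a2 and Col6a1 (0.82 ± 0.06, SE) were higher, and Col15a1 (-0.92 ± 0.06) and the basement membrane collagen Col4a1 (-0.85 ± 0.07) were lower. Of 29 inflammatory cytokines and chemokines, 4 rose and 4 fell (5 and 5 adjusted over the list alone; adjusted p = 0.891): the monocyte chemoattractants Ccl7 (1.11 ± 0.13) and Ccl2 (0.92 ± 0.12) were higher, and Lcn2 (-0.94 ± 0.07) and Cxcl16 (-0.77 ± 0.07) were lower. IL-4 receptor and signalling components gave 3 rises and 3 falls among 20 (0.21), phagocytosis and lysosomal clearance 3 and 3 among 31 (0.989), interferon-stimulated genes 1 and 2 among 34 (0.828), cholesterol biosynthesis 2 and 1 among 16 (0.322), immediate early and heat shock genes 3 and 2 among 20 (0.876) and ribosomal proteins 1 and 1 among 18 (0.821), each with its camera adjusted p. Adjusted over the list alone these counts were 4 and 3 for receptor and signalling components and 3 and 4 for immediate early and heat shock genes, and were the same for the other 4. For the phagocytosis and the immediate early lists the median, the mean and the test differed in sign. Markers of other cell types did not pass camera as lists: myogenic cells had 1 rise and 1 fall among 24 (0.891), macrophages and leukocytes 0 and 2 among 23 (0.557), endothelium 2 and 1 among 17 (0.497), pericytes and smooth muscle 1 and 2 among 13 (0.607) and tenocytes and Schwann cells 0 and 1 among 10 (0.708). Adjusted over the list alone the tenocyte and Schwann cell count was 0 and 0, and the other 4 were the same. By fry, which does not compare a list with other genes, the receptor and signalling components passed upward (adjusted p = 5.55e-11), with a mean log2 change of 0.149. The endothelial (fry adjusted p = 9.36e-06, upward), pericyte (0.0236, downward) and leukocyte (0.029, downward) markers passed fry as well. The mean of the endothelial markers lay at -0.036 to -0.016 on wild-type vehicle arrays and 0.026 to 0.074 on wild-type IL-4 arrays. That of the leukocyte markers lay at -0.003 to 0.011 and -0.066 to -0.043. Single members of these lists still moved, such as the lysozyme gene Lyz2, which fell by 1.07 ± 0.07 (2 of 3 probes), and Flt1, a vascular endothelial growth factor receptor, which rose by 1.22 ± 0.07 (1 of 2 probes).

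**Figure D2:**
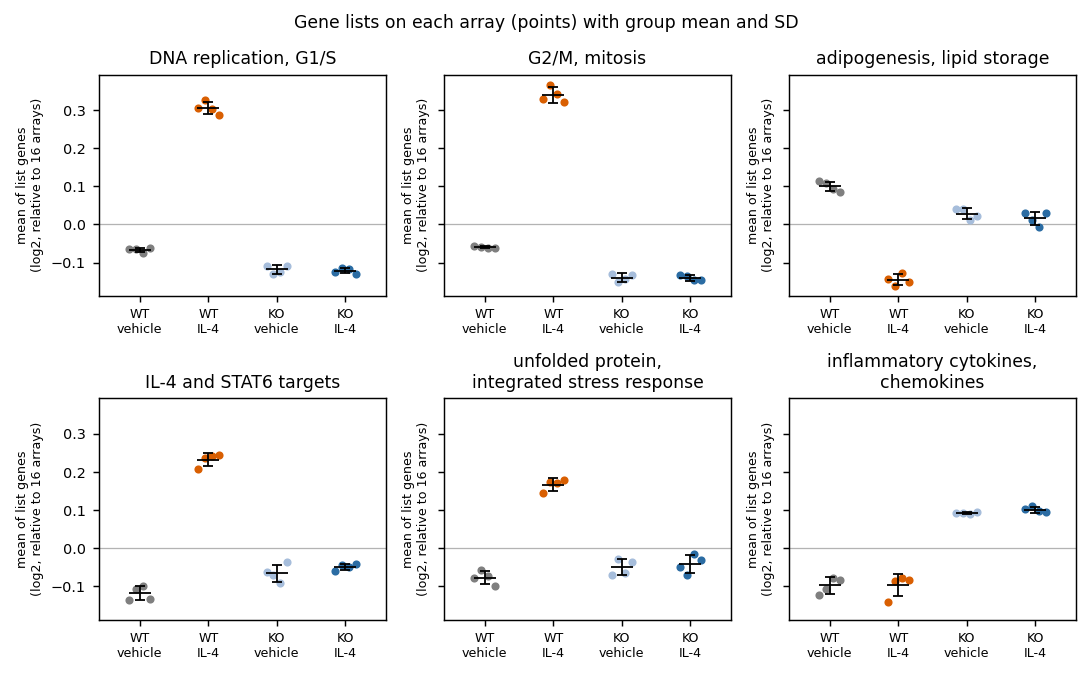
Mean of the genes of 6 lists on each array, relative to their mean over the 16 arrays (vertical axis, log2 units), in the 4 groups; points are arrays, and bars give the mean and SD of the 4 arrays of a group. The DNA replication list stood at 0.305 ± 0.017 in wild-type IL-4 arrays against -0.066 ± 0.006 in wild-type vehicle arrays, and the inflammatory list at 0.093 ± 0.002 in knockout vehicle arrays against -0.097 ± 0.022 in wild-type vehicle arrays.

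The second comparison asked whether FAPs without the receptor respond to IL-4. In the knockout 0 of 25697 probes passed in limma, and the smallest adjusted p was 0.288. At an unadjusted p under 0.05 there were 1439 probes, or 5.6% where 5% come by chance, and limma with a trended, robust variance model called 1 probe, unnamed here (log2 change 0.48, adjusted p = 0.0171). Of the 24 genes named for wild type, 23 had a 95% confidence interval of the knockout change that included 0. The exception was Agtr1a, at 0.24 with an interval from 0.11 to 0.38 before adjustment. The knockout log2 change was 0.05 for Car4 (interval -0.05 to 0.16), 0.06 for Ccl11 (-0.13 to 0.26) and -0.02 for Cish (-0.09 to 0.05). Pdgfra, the surface marker by which FAPs are commonly identified, had a knockout change of 0.39 ± 0.11 (SE) with a limma adjusted p of 0.81. Of the 20 lists, 0 passed (camera adjusted p from 0.226 to 0.989), and 0 of their members did. Adjusted over the list alone, 1 member fell in each of the receptor and signalling, extracellular matrix and secreted factor lists. The interferon list passed without knockout vehicle array 2 (median 0.03, camera adjusted p = 2.75e-05 with the preset correlation), but not with an estimated correlation (adjusted p = 0.307).

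The difference of the responses, wild type minus knockout, was tested as an interaction. It passed for 2156 probes, 1038 with a higher and 1118 with a lower change in wild type, among them all 24 genes named above. Car4 differed by 4.28 ± 0.07 (SE), Ccl11 by 3.02 ± 0.13 and Itga11 by -1.73 ± 0.08 (limma adjusted p = 2.52e-14, 1.34e-09 and 3.11e-09). Over the 3510 probes called in wild type, the median size of the change was 0.24 in wild type and 0.032 in the knockout, 50.6% had the same sign in the knockout, and 2055 (58.5%) passed the interaction. The lists of DNA replication (median difference 0.36), G2/M (0.24), adipogenesis (-0.20), IL-4 and STAT6 targets (0.02) and the unfolded protein and integrated stress response (0.11) passed camera and held with an estimated correlation, with adjusted p-values there of 5.48e-06, 1.23e-06, 0.00059, 0.0122 and 0.00314. Their members with a higher and a lower change in wild type numbered 30 and 0, 29 and 0, 0 and 15, 9 and 1, and 6 and 0, or, adjusted over the list alone, 33 and 2, 32 and 0, 0 and 19, 9 and 1, and 10 and 0. Secreted factors acting on myogenic cells (2 higher and 6 lower, or 2 and 9 over the list alone; median difference -0.02) passed with the preset correlation (camera adjusted p = 0.0308), a call lost with an estimated correlation (adjusted p = 0.054) and without wild-type IL-4 array 5 (0.0524). None of the lists of other cell types passed camera here (adjusted p from 0.325 to 0.957). By fry the endothelial markers passed upward (2 of 17 higher and 0 lower, adjusted p = 0.000124). The tenocyte and Schwann cell markers passed fry downward (0 of 10 higher and 0 lower, adjusted p = 0.0103).

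**Figure D3:**
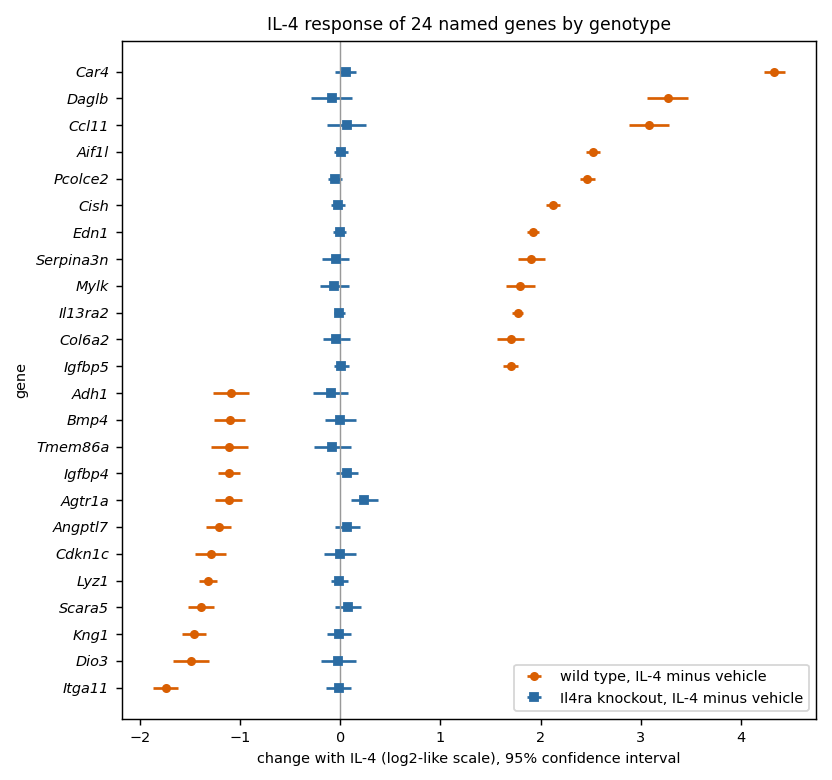
Change with IL-4 (horizontal axis, log2-like scale) of the 24 genes with the largest wild-type changes; circles are wild type and squares the Il4ra knockout, with 95% confidence intervals from limma. Wild-type changes run from -1.74 for Itga11 to 4.33 for Car4, and the knockout intervals of 23 genes include 0.

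The third comparison asked how the genotypes differ under vehicle. Mmp3, the matrix metalloproteinase stromelysin-1, stood at 11.72 ± 0.10 in knockout and 9.82 ± 0.18 in wild-type arrays (SD, n = 4 each), 3.73-fold higher in the knockout (log2 difference 1.90 ± 0.08, SE; limma adjusted p = 1.12e-08). Lbp, the lipopolysaccharide binding protein, was 2.38-fold and the chemokine Cxcl14 2.07-fold higher, with log2 differences of 1.25 ± 0.08 and 1.05 ± 0.06. Pde1a (0.96), the proteoglycan Dcn (0.80), Serpina3n (0.73), Glo1 (0.72) and the neutrophil chemoattractant Cxcl1 (0.68) were also higher. Lower in the knockout were Ces1d, a carboxylesterase at 0.501 times the wild-type level, Rtf2 (-0.90), Art3 (-0.87), Tmem45b (-0.78), the transferrin gene Trf (-0.61), Acaa2, an enzyme of mitochondrial fatty acid oxidation (-0.58), Cox8b, a subunit of cytochrome c oxidase (-0.57), and Agpat2, an enzyme of triglyceride synthesis (-0.56). In all, 690 probes passed in limma, 304 higher and 386 lower in the knockout, of which 22 reached 1.5-fold. With the trended, robust variance model the balance turned to 394 higher and 375 lower. The count was 447, 426 and 456 without wild-type vehicle arrays 1, 2 and 4, and 385 without knockout vehicle arrays 2 and 3, which lay at -6.95 and -7.52 on the third principal component; that last setting was chosen after seeing the data.

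Inflammatory cytokines and chemokines were higher in knockout vehicle arrays, with 8 of 29 higher and 0 lower (10 and 0 adjusted over the list alone; median 0.03; camera adjusted p = 3.69e-08, and adjusted p = 0.00129 with an estimated correlation), led by Cxcl14 and Cxcl1. The mean of the macrophage and leukocyte markers was 0.016 to 0.038 in the knockout vehicle arrays and -0.003 to 0.011 in the wild-type vehicle arrays, with 2 of 23 markers higher and 0 lower (2 and 0 over the list alone; camera adjusted p = 0.167). These 2 were Cd14 (0.24), whose call ended with only the groups compared or with the replicate block, and Cd74 (0.08), whose call ended there and without single arrays. G2/M genes were lower, 11 of 46 with 0 higher (12 and 0 over the list alone; median -0.04; camera adjusted p = 2.51e-08, and adjusted p = 0.00059 with an estimated correlation), with Cenpa at -0.39 ± 0.05 (SE) and the mitotic kinase Cdk1 at -0.24 ± 0.03 (1 of 3 probes). DNA replication genes were lower, 4 of 43 with 0 higher (7 and 0 over the list alone; median -0.04; camera adjusted p = 5.88e-05, and 0.0176 with an estimated correlation), with Mcm5 at -0.19 ± 0.03. Adipogenesis genes were lower, 4 of 38 with 0 higher (4 and 1 over the list alone; median -0.03; camera adjusted p = 0.00342, and 0.029 with an estimated correlation), with Pnpla2 at -0.24 ± 0.03 and the hormone-sensitive lipase Lipe at -0.33 ± 0.05 (1 of 2 probes). Ribosomal protein genes shifted up by a median of 0.09 (camera adjusted p = 0.00225, and 0.0258 with an estimated correlation), although of 18 only 1 passed higher, Rpl10 (0.29 ± 0.04), and 1 lower, Rps2 (-0.18 ± 0.04); 6 and 1 passed over the list alone. The call for Rps2 ended without any 1 of knockout vehicle arrays 2, 3 and 4 or wild-type vehicle arrays 1, 2 and 4. FAP identity genes shifted up by a median of 0.06 (2 higher and 1 lower, or 5 and 1 over the list alone; camera adjusted p = 0.0139), a call lost with an estimated correlation (adjusted p = 0.0892), without wild-type vehicle array 4 (0.0528) and without knockout vehicle arrays 2 and 3 (0.0549). The IL-4 and STAT6 target list did not pass (median 0.005, camera adjusted p = 0.322), and neither did the lists of other cell types by camera. By fry 3 of the latter passed. The pericyte and smooth muscle markers passed downward (2 of 13 lower and 0 higher; adjusted p = 0.0113), and so did the myogenic markers (2 of 24 lower and 0 higher; 0.0149). The endothelial markers passed upward (0 of 17 higher and 0 lower; 0.0184). Their counts were the same over the list alone. The mean of the pericyte and smooth muscle markers lay at -0.052 to 0.009 on knockout vehicle arrays and 0.024 to 0.064 on wild-type vehicle arrays. That of the myogenic markers lay at -0.013 to 0.009 and 0.013 to 0.018, and that of the endothelial markers at -0.012 to -0.005 and -0.036 to -0.016. Without knockout vehicle arrays 2 and 3 and with an estimated correlation, a setting chosen after seeing the data, the DNA replication (adjusted p = 0.126), adipogenesis (0.0997) and ribosomal protein (0.128) lists lost their calls.

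The fourth comparison set knockout against wild type under IL-4. It gave the most calls of the 5 contrasts, 3830 probes in limma, with 1979 higher and 1851 lower in the knockout. Mmp3 was 6.77-fold higher in the knockout (log2 difference 2.76 ± 0.08, SE), followed by Kng1 (2.07), Angptl7 (1.85), Itga11 (1.69), Scara5 (1.67), Agtr1a (1.66), Lbp (1.62) and Dio3 (1.60). Car4 (-4.29 ± 0.05), Daglb (-3.37), Ccl11 (-2.80), Pcolce2 (-2.63), Aif1l (-2.53), Cish (-2.31), Col6a2 (-2.18) and the cytokinesis gene Prc1 (-1.91) were lowest relative to wild type. Limma adjusted p-values were 5.26e-12 for Mmp3 and 1.78e-16 for Car4. DNA replication genes (33 of 43 lower, 35 adjusted over the list alone, median -0.40) and G2/M genes (33 of 46 lower, 34 over the list alone, median -0.26) were lower in the knockout, with camera adjusted p = 9.31e-34 and 8.65e-33. Adipogenesis genes were higher (13 of 38 with 1 lower, 15 and 1 over the list alone, median 0.11; camera adjusted p = 9.18e-06), as were secreted factors acting on myogenic cells (10 of 23 with 3 lower, 10 and 3 over the list alone, median 0.02; 0.000937) and inflammatory genes (11 of 29 with 2 lower, 11 and 3 over the list alone, median 0.01; 0.00437). Of 23 macrophage and leukocyte markers 4 were higher and 0 lower (5 and 0 over the list alone), among them Lyz2 (1.29), and of 10 tenocyte and Schwann cell markers 3 were higher and 0 lower (3 and 0 over the list alone). As lists these did not pass camera (adjusted p = 0.338 and 0.0748) and passed fry, which does not compare them with other genes (0.00289 and 3.69e-05). Of 17 endothelial markers 2 were higher and 2 lower (2 and 2 over the list alone). They passed fry downward (0.000124) and did not pass camera (0.821). IL-4 and STAT6 targets (10 of 34 lower and 2 higher, 11 and 2 over the list alone; 0.000858) and the unfolded protein and integrated stress response (10 of 21 lower and 1 higher, 10 and 2 over the list alone; 0.000487) were lower. The 7 lists named here that passed camera held with an estimated correlation, while the ribosomal protein list (4 of 18 higher and 0 lower, 5 and 0 over the list alone; median 0.12, camera adjusted p = 0.03) did not (adjusted p = 0.0882). That call also ended without knockout IL-4 array 4 (0.0816) or wild-type IL-4 array 5 (0.0621) and in the brighter part of the probes (0.138). With an estimated correlation the inflammatory list was lost without knockout vehicle array 2 (adjusted p = 0.0553), as were it (0.0965) and the IL-4 and STAT6 target list (0.0769) without arrays 2 and 3, settings chosen after seeing the data.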

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

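The tests of other splits of the arrays, of low sensitivity, of a batch, of the probes and gene groups called at baseline, of the target list and of probe noise were chosen after the results were seen. The split-control test over all probes, the chromosome test and the bounds of the leukocyte test were set before, and the spread of the leukocyte correlation was computed only after its value was known, which changed the reading of that test. Genes named below for the interferon pattern were chosen after their values were seen.

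Some arrays stood far from the other 3 of their group, by the gap to the nearest divided by the range. There were 11 such cases among 280 groups tested, and chance gives about 1 in 20. Among genes they were Daglb in knockout vehicle array 2 (9.24 against 8.99 to 9.01, ratio 0.921), Kng1 in wild-type vehicle array 2 (0.954), Scara5 (0.854) and Pde1a (0.854) in knockout vehicle array 4, Ces1d in knockout vehicle array 2 (0.902), the brighter Ccl11 probe in wild-type vehicle array 1 (10.58 against 11.01 to 11.05, ratio 0.92) and Socs1 in knockout IL-4 array 1 (0.914). Among lists they were IL-4 and STAT6 targets (0.838) and inflammatory genes (0.887) in wild-type IL-4 array 5, and secreted factors acting on myogenic cells in knockout vehicle array 3 (0.88) and knockout IL-4 array 4 (0.905).

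The IL-4 response differed between genotypes for 2156 probes and for 6 lists, whose median difference of wild type minus knockout was 0.019 for IL-4 and STAT6 targets, 0.359 for DNA replication, 0.241 for G2/M, -0.201 for adipogenesis, -0.024 for secreted factors acting on myogenic cells and 0.113 for the unfolded protein and integrated stress response; the secreted factor list was lost with an estimated correlation (adjusted p = 0.054). Low sensitivity as the reason for the 0 knockout calls is argued against by the slope of knockout on wild-type change over the probes called in wild type, which was at most 0.0057 with any array left out, where an equal response would give 1. An unrecorded batch of the wild-type IL-4 arrays as the whole cause is argued against by the rise of the target list fixed beforehand (camera with an estimated correlation, p = 0.00163). A batch that adds to the response cannot be excluded, since no chip was given. Replicate numbers run from 1 to 4 on wild-type vehicle arrays and from 5 to 8 on wild-type IL-4 arrays. Both knockout groups are numbered 1 to 4. Treatment thus goes with a separate set of replicates in wild type only, which also limits the difference of the responses. Whether these numbers mark separate cultures or mice was not given. That the knockout cultures do not signal in response to IL-4 remains a hypothesis.

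Calls were also counted for other splits of the arrays into groups of the same size. For the wild-type response 1 of 35 splits, the real one, gave as many calls (3510, highest other 9). The same held for the genotype under vehicle (1 of 35, 690 calls, highest other 2) and under IL-4 (1 of 35, 3830 calls, highest other 1). With 35 splits, 1 of 35 is the smallest share possible, so this argues against chance without excluding it. A split that mixes the real groups also adds their difference to the residual spread, which lowers its count whatever caused the difference. For the knockout response any split reaches the real count of 0 (35 of 35, highest other 2), so the count of splits says nothing about chance. For the difference of responses 1 of 100 assignments reached 2156, and the highest other gave 2060. That other draw was the 1 of 99 that kept or exchanged the wild-type treatment labels whole, and the remaining draws called at most 1 probe. Shuffling treatment within genotype breaks the wild-type response itself. The count therefore argues against chance only for there being no response in either genotype, and does not test equal responses.

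The cell-cycle lists were lower and the list of inflammatory cytokines and chemokines higher in knockout vehicle arrays. Tonic IL-4 receptor signalling in the wild-type cultures predicts that baseline differences oppose the IL-4 response. The wild-type controls were split so that no array served both changes. The correlation across all probes was then 0.053 on average (0.039 to 0.071 over 6 assignments). Of the 178 to 360 probes called at baseline 44% were opposite (40.8% to 46.6%). These 2 measures argue against tonic signalling as the main cause. Over the probes called at baseline, however, the correlation of the 2 changes was weakly negative in all 6 assignments (-0.1 to -0.024). That is the predicted direction, so tonic signalling is not excluded. The all-probe test dilutes the genes in question. The cell-cycle part stays open. The 4 to 8 cell-cycle genes called in each split were opposite in 100% of cases. That decides nothing, since 64 list genes rose and 1 fell with IL-4 and 15 were lower and 0 higher at baseline. The 4 to 5 genes called of the inflammatory list were opposite in 64.2% on average (50% to 80%). The mean of that list was -0.097 ± 0.022 (SD) in wild-type vehicle, -0.097 ± 0.029 in wild-type IL-4 and 0.093 ± 0.002 in knockout vehicle arrays. Tonic signalling predicts a fall of this mean with IL-4. None was seen, which argues against it for the list mean. Of single members 4 rose and 4 fell with IL-4, so for these the question stays open. The IL-4 and STAT6 target list gave a camera p of 0.233 in the upward direction, which leaves open whether tonic signalling acts through it. Genes called at baseline were not crowded along the chromosomes. Of the 611 called and placed, 0% lay in crowded windows of 25 neighbouring genes (fullest window 6 calls, shuffled 95th percentile 7). Of 24 neighbours of Il4ra 0 were called. With 611 of 16579 placed genes called, few calls would come among 24 genes anyway, so this count decides little. The lack of crowding argues against 1 segment holding most of the called genes. A segment of 25 genes could, however, hold only a few of them. A linked variant that acts on genes elsewhere would leave no crowding, so a linked segment as the main cause stays open. Separate litters or passages of the genotypes were not tested.

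Interferon-stimulated genes varied together between arrays of a group. Their list stood at 0.173 in knockout vehicle array 2 against -0.085 to -0.026 in the other 3, with Isg15 at 8.75 against 7.97 to 8.05. Probe noise is argued against by a residual correlation of 0.306, above the highest of 1000 random lists matched on signal (0.071). Whether leukocytes in some cultures are a source was tested with the deviations of the interferon and leukocyte lists over 16 arrays. These gave r = 0.037 (permutation p = 0.905) and rho = -0.14 (p = 0.653), 1 relation tested, and r = -0.181 without the 2 arrays farthest from the median. The value is under the bound of 0.25 set beforehand, but its jackknife SE of 0.4 leaves it undecided. The leukocyte genes Ptprc, Adgre1 and Tyrobp lay at 7.82, 7.81 and 7.81 in knockout vehicle arrays, near the array minimum. They were picked from 23 measured markers, of which 2 were higher and 0 lower in knockout than in wild-type vehicle arrays.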

How the results depend on the processing

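Counts of called probes kept within 1.5 times of their values with all arrays under filters on dim probes, the offset, array weights and fits of only the groups compared. The last of these was not run for the difference of responses, which uses all 4 groups. Renewed quantile normalization and median centring could change nothing on arrays that already share 1 distribution, and say nothing about stability. A 1.5-fold threshold left 343 probes for the wild-type response, 353 for the difference of responses, 22 for genotype under vehicle and 393 for genotype under IL-4, and an adjusted p under 0.01 left 1266 for the difference and 245 for genotype under vehicle; these thresholds are stricter by construction. The trended, robust variance model called 1 probe in the knockout response in place of 0 and, for genotype under vehicle, 394 higher and 375 lower in place of 304 and 386, and fry called 47 list shifts in place of 27, as it does not compare a list with other genes; with an estimated correlation there were 23. Each array left out gave 3002 to 3606 calls for the wild-type response, 0 to 0 for the knockout, 1846 to 2236 for the difference, 426 to 823 for genotype under vehicle, 3227 to 3914 for genotype under IL-4 and 26 to 30 list shifts. The count for genotype under vehicle fell by over 1.5 times without wild-type vehicle arrays 1 (447), 2 (426) or 4 (456). Without knockout vehicle arrays 2 and 3, chosen after seeing the data, it was 385, and the interferon list in that contrast reversed to a median of -0.036 (adjusted p = 0.026); the interferon list then also passed in the knockout response (median 0.046, adjusted p = 1.98e-06), as it did without knockout vehicle array 2 alone (0.033, 2.75e-05), and in the difference of responses (-0.036, 0.0307), while the tenocyte and Schwann cell list passed in the knockout response (0.037, 0.026). With an estimated correlation, also chosen after seeing the data, none of these 5 calls held (adjusted p = 0.617, 0.254, 0.307, 0.619 and 0.0873), and list shifts numbered 18 without both arrays and 22 without array 2. Fewer arrays lower a count in part by construction, and for the other changes the cause was not tested. Arrays with the same replicate number were correlated across probes after the group mean of each probe was removed, and these residual correlations were low. For knockout vehicle and IL-4, r was 0.137, 0.052, -0.054 and -0.217. For the vehicle groups it was 0.048, -0.032, -0.006 and -0.078. For wild-type vehicle and knockout IL-4 it was -0.005, -0.017, 0.08 and 0.163. The numbers were therefore not taken to pair arrays. With the replicate block the knockout response kept 0 calls and genotype under vehicle had 354. In these fits 19 named genes lost their call, among them Mcm5 (limma adjusted p = 0.053), Lipe (0.0537) and Rps2 (0.0797). For genotype under vehicle this block joins knockout and wild-type arrays by number alone, with no known shared unit, and uses up degrees of freedom. The calls lost there come in part by construction and are weak evidence on these genes. Over all alternatives, results for named genes were the same in 6397 cases, lost their call in 286 and gained one in 2. For lists these counts were 2763, 25 and 31, with 1 reversal. The counts of the same results include 268 genes and 100 list tests under each of renewed quantile normalization and median centring, which were fixed to be the same. Chip as a block was not run, as no chip was given, and neither were the checks of Il4ra, which had no named probe. Signal over background was not given, so changes of genes near the array minimum are the least certain.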

Other observations

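All tests and genes below were chosen after the data were seen. Genes sharing a symbol stem were grouped into 271 families of at least 8 measured genes. Some stems that join unrelated or unnamed genes and receptor families of smell were left out. Stems that were kept can still join genes of unlike function. The Cdc stem, for instance, holds Cdc20 and Cdc42ep2, and the Sec stem holds Sec61b and Sec14l1. The families were tested with camera for the response of each genotype and for genotype under vehicle. With IL-4 in wild type the Mcm family, subunits of the replicative helicase and relatives, rose in 7 of 10 genes (median log2 change 0.42, adjusted p = 4.91e-09, and adjusted p = 0.0473 with an estimated correlation). The genes that rose, Mcm2 to Mcm7 and Mcm10, also belong to the DNA replication list above, so this largely repeats that result. Other families passed with the preset correlation and were lost with an estimated one. A minority of members was lower in Cox, a stem mostly of cytochrome c oxidase subunits (11 of 27 lower, 0 higher). Its camera adjusted p was 0.00041, and 0.267 with an estimated correlation. Among these 11 were Cox10, Cox14, Cox15, Cox17, Cox19 and Cox20, which are not subunits of the oxidase. A minority was also lower in Mrpl, mitochondrial ribosomal proteins (15 of 47 lower, 0 higher, 0.000134 and 0.267), and Ndufa, subunits of complex I (4 of 12 lower, 0 higher, 0.0143 and 0.23). Of the peroxisomal Pex genes 7 of 14 were lower and 0 higher (0.00638 and 0.23), and of the Sec genes, many of them of the secretory pathway, 8 of 24 were higher and 0 lower (0.00203 and 0.125). The Mrps family also passed downward (9 of 29 lower, 0 higher), and the Fkbp (5 of 11 higher, 0 lower), Tubb (4 of 8 higher, 0 lower), Kif (7 of 27 higher, 2 lower) and Cdc (10 of 28 higher, 2 lower) families upward, with adjusted p-values of 0.583, 0.23, 0.362, 0.215 and 0.477 with an estimated correlation. Under vehicle, Rpl genes of the large ribosomal subunit were higher in the knockout (7 of 37 higher, 0 lower, median 0.08). The camera adjusted p was 1.44e-06, and 0.0473 with an estimated correlation. Rpl5, Rpl10 and Rpl37, among others, also belong to the ribosomal protein list above. That list lost its call without knockout vehicle arrays 2 and 3 and with an estimated correlation (camera adjusted p = 0.128). The 2 results under vehicle thus overlap. The Cxcl (3 of 13 higher, 0 lower), Mmp (4 of 20 higher, 0 lower) and Ccl (2 of 23 higher, 0 lower) families passed upward there with the preset correlation, and the Cox (5 of 27 lower, 1 higher) and Kif (4 of 27 lower, 0 higher) families downward (adjusted p = 0.000166, 0.0012, 0.0248, 0.0311 and 0.0462) and were lost with an estimated correlation (adjusted p = 0.215, 0.23, 0.23, 0.657 and 0.267).

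Replication histone genes did not move as one family with IL-4 in wild type (45 genes, 9 higher and 6 lower, adjusted p = 0.969). The 9 rises were among the 14 H2ac genes, with H2ac7 at 1.13, H2ac12 at 0.91 and H2ac15 at 0.87, and 1 H2ac gene fell. Of 12 H2bc genes 0 rose and 4 fell, H2bc7 by 0.41, H2bc11 by 0.39, H2bc9 by 0.38 and H2bc12 by 0.22. Of 19 H3c and H4c genes 0 rose and 1 fell. The family members are near-identical in sequence, so probes cannot be assigned to a single gene with certainty, and no difference between histone types was tested.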
